A study of Homo sapiens and Mus musculus with 56 samples.

How the data were processed

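Gene expression was measured on 56 Affymetrix whole-transcript gene arrays. According to the labels, 28 human arrays hold cultured cells of 5 human glioblastoma lines (SF295, U118, U87M2, DBM2 and U251M2) and 28 mouse arrays hold subcutaneous tumours of the same lines in nude mice. Cells or mice received vehicle or V-4084 for 7 days. The labels describe V-4084 as a selective small-molecule inhibitor of the MET kinase, given to mice at 30 mg per kg. For cells the labels state a stock of 0.01 M in DMSO, and the final concentration is not given in the sources used here. Tumours were started from 500000 cells, and 200 ng of RNA was labelled per array. Each array was assigned to its group by the title of its label. The titles of 3 human arrays read DBM2 with V-4084, while their source and cell line fields read SF295. They were placed with DBM2, and the average and the differences between lines were also computed without that line.

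The deposited values are log2 probe-set intensities that the authors made with RMA and Partek, whose versions are not given in the sources used here. Maxima near 14 lie below 16, the log2 limit of a 16-bit scanner, and array medians were nearly equal within a platform. Values were used as deposited. The human platform has 33297 probe sets, of which 19460 name 1 gene, 1754 name several and 12083 name none. The mouse platform has 35556 probe sets, of which 21789 name 1 gene, 1621 name several and 12146 name none. Probe sets naming several genes or none were left out. Of several probe sets for a gene, the one with the highest mean over the platform was used, which gave 18417 human and 19938 mouse genes. For arrays there is no depth to report, and the number of arrays limits the precision.

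The comparisons, gene lists, rules for naming genes and alternatives were fixed before the data were examined, apart from those named as later choices. For each platform, limma 3.58.1 in R 4.3.3 fitted the means of the 10 groups (18 residual degrees of freedom, lmFit and eBayes without trend). Contrasts gave the V-4084 effect in each line, the average of the 5 within-line effects with equal weights, an F test of differences between the 5 effects and an F test of differences between the 5 vehicle groups. P-values are two-sided and adjusted by Benjamini-Hochberg (BH) over the genes of 1 contrast, and genes at an adjusted p under 0.05 were called. An error given with a log2 difference is limma's standard error (SE), and one given with a level is the standard deviation (SD) over arrays. The labels do not state that the repeats of a group were separate cultures or animals, so every p-value describes differences between arrays. Human and mouse arrays were never fitted together.

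The 16 pathway lists were HGF-MET axis, MAPK output, FOXO targets, G1/S cell cycle, G2/M cell cycle, interferon response, antigen presentation, hypoxia and glycolysis, cholesterol synthesis, ATF4 and unfolded protein response, extracellular matrix and TGF-beta targets, inflammatory cytokines and NF-kB, p53 targets, neural and glial identity, growth factor receptors and ligands, and angiogenesis. The 14 cell type lists were endothelial, pericyte and smooth muscle, fibroblast, macrophage and monocyte, neutrophil, natural killer and T cell, B cell and plasma cell, dendritic cell, mast cell, adipocyte, skeletal muscle, keratinocyte and hair, erythroid, and Schwann and nerve. Mouse genes were matched by symbol. Lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 30 lists for the average and over 30 lists and 5 lines for single lines. Camera asks whether the genes of a list move more than the other genes. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move, on balance, in 1 direction, without comparing them with other genes.

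Genes were named by rule. HGF and MET are given in every comparison. For the average, the rule took the 10 largest increases and 10 largest decreases among called genes with the same sign in all 5 lines, and where fewer than 5 passed in a direction, the 5 with the smallest p. For each line it took 4 in each direction among called genes whose V-4084 and vehicle arrays did not overlap. It took the 6 smallest p for differences between lines, the 5 smallest for vehicle levels, up to 4 members of each described list and up to 10 shared genes. Predicted genes, olfactory receptors, pseudogenes and small RNA genes were counted but not named.

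The response on both platforms was compared over 14334 symbols present on both, with Fisher's exact test of the overlap of calls in each direction. Genes are not independent, so those p-values describe the overlap only. Chosen after the data were seen were the comparison of same-numbered arrays of the 2 platforms, also for each treatment, the comparison of line profiles across platforms, the contrast of U87M2 with the mean of the other lines, the fits without the U87M2 line or without 3 human arrays with a narrow range of values, and a fit of the mouse arrays with a skeletal muscle score as covariate. The score is the mean log2 value of the list. For same-numbered arrays, each score was centred on its group, and labels were permuted within groups 100000 times.

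Alternatives fixed in advance were genes above the median of mean levels, the average of several probe sets, quantile normalization, centring on array medians, eBayes with trend and robust settings, array weights, a block for the repeat number, a fold filter of 1.5, fits of a line alone, a fit without DBM2, and leaving out each array. Array weights used limma's gene-by-gene method on both platforms, since the REML method did not converge on the human arrays. Within a platform, correlations of same-numbered vehicle and V-4084 arrays ran from -0.520 to 0.318, so the numbers were not taken to pair arrays. The fits were tested on simulated data: of genes changed 2-fold in U87M2, 94.0% were recovered on human and 100% on mouse arrays, of those changed 1.5-fold 56.7% and 73.1%, and with no change none was called. The simulated noise was independent between genes and arrays and held no deviations of whole arrays, so these rates need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.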

Results

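The labels give 28 human arrays as cultured cells and 28 mouse arrays as tumours grown in mice, each from 5 glioblastoma lines treated with vehicle or the MET inhibitor V-4084. Groups held 3 arrays, except 2 with vehicle and 2 with V-4084 for SF295 on human arrays, 2 with vehicle for SF295 on mouse arrays, and 2 with V-4084 for U251M2 on mouse arrays. Array medians ran from 6.63 to 6.87 (log2) on human and from 6.11 to 6.31 on mouse arrays. The SD of the values within an array ran from 1.75 to 2.10 on human and from 1.76 to 1.88 on mouse arrays. The array nearest to each of the 56 belonged to its own line, including the 3 human arrays whose label fields name both DBM2 and SF295. A narrow range was found on 3 human V-4084 arrays, with an SD of 1.75 (DBM2, repeat 2), 1.90 (U251M2, repeat 1) and 1.90 (SF295, repeat 2), against at least 2.03 on every vehicle array. Their deviations from their groups correlated across genes with gene level at r = -0.587, -0.536 and -0.272, so dim genes lay higher on them. Genes are not independent replicates.

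**Figure D1:**
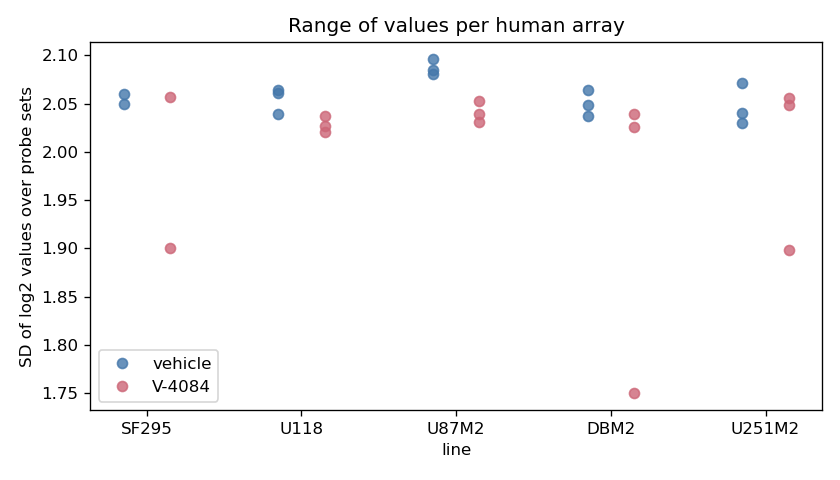
Standard deviation of the log2 values over all probe sets (y axis) for each human array, by line (x axis) and treatment; each point is 1 array. The V-4084 arrays at 1.75, 1.90 and 1.90 lie below all vehicle arrays, whose lowest value is 2.03.

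In muscle genes, the human arrays labelled as cultured cells varied within their groups together with the mouse arrays of the same line, treatment and repeat number. For the skeletal muscle list, which holds contractile genes, the within-group deviations of the 27 same-numbered pairs gave Pearson r = 0.954 (permutation p = 2e-05, BH-adjusted p = 0.0006 over 30 lists) and Spearman rho = 0.935 (permutation p = 1e-05, the smallest the permutations can give). Without the 2 pairs farthest from the median r was 0.946, with vehicle alone 0.947 and with V-4084 alone 0.957. All 16 muscle genes measured on both platforms had a positive r, with a median of 0.830 and 0.957 for ATP2A1, a calcium pump of muscle that was, like CKM below, chosen after its values were seen. Muscle levels on human arrays were low: CKM, muscle creatine kinase, ran from 5.81 to 7.41, and 3 of 16 muscle genes had a mean above the platform median of 7.12. On mouse arrays Ckm ran from 6.89 to 10.72. The fibroblast list also tracked (r = 0.724, permutation p = 0.00225, adjusted p = 0.0337; rho = 0.623, permutation p = 0.005; 0.513 without the 2 farthest pairs), with r = 0.853 for vehicle and 0.343 for V-4084. The macrophage and monocyte list had r = 0.507 (adjusted p = 0.0731), and 2 of 30 lists passed. Across the 14318 genes outside the muscle list, the mean r of same-numbered arrays was 0.228 for vehicle (one-sided permutation p = 0.00122; -0.123 for other numbers) and -0.024 for V-4084 (one-sided permutation p = 0.657; 0.012 for other numbers). These are correlations across genes, which are not independent replicates. Deviations are centred within groups, so the value for other numbers tends to the opposite sign and is no separate finding. Because same-numbered arrays varied together, the arrays are named below by platform, and the platforms are not treated as independent.

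**Figure D2:**
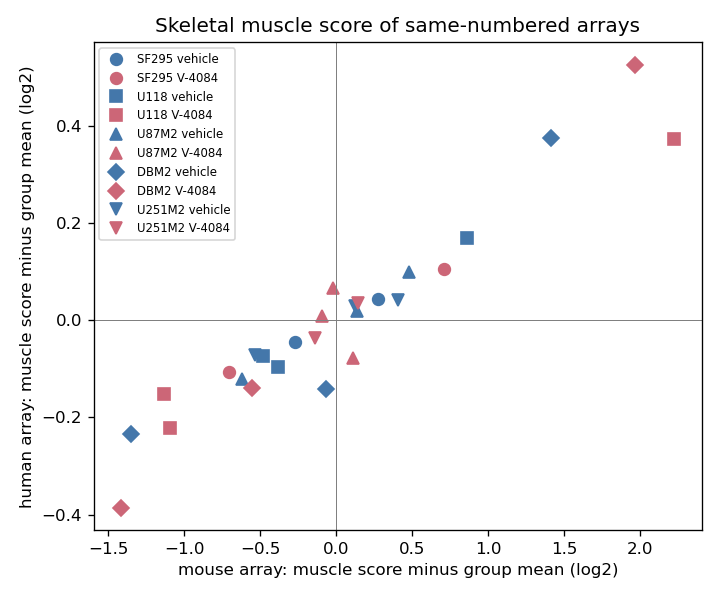
Skeletal muscle score (mean log2 value of the list) minus its group mean, on mouse arrays (x axis) and on the human arrays of the same line, treatment and repeat number (y axis). Each of the 27 points is a pair, coloured by treatment and shaped by line; r was 0.954.

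Vehicle arrays show how the lines differ without V-4084 in the ligand and the receptor that V-4084 targets. HGF, the ligand of MET, was high on the human vehicle arrays of U87M2 (11.46 ± 0.06, SD, n = 3), U118 (10.20 ± 0.18, n = 3) and SF295 (10.03 ± 0.17, n = 2), and low in DBM2 (5.37 ± 0.06, n = 3) and U251M2 (5.14 ± 0.07, n = 3). MET, its receptor, lay at 10.88 in SF295, 10.69 in U118, 10.60 in U87M2, 10.43 in DBM2 and 8.77 in U251M2. Both differed between lines by limma's F test (adjusted p = 6.17e-25 for HGF and 4.32e-11 for MET). The other human genes with the smallest p were AHR, the aryl hydrocarbon receptor, PTPRZ1, a receptor phosphatase of glial cells, EFEMP1, a matrix protein, and COLEC12, a scavenger receptor. AHR ran from 4.68 in DBM2 to 11.47 in SF295, PTPRZ1 lay at 11.09 in U251M2 and at 5.66 or less in the other lines, EFEMP1 was highest in U251M2, lay at 10.05 in DBM2 and at 5.74 or less in the others, and COLEC12 ran from 5.68 in U87M2 to 10.22 in U118. In all, 10764 of 18417 human genes differed between lines. On mouse arrays 10833 of 19938 genes differed, led by Hoxd10, Hmcn1, Aqp1, Cnksr2 and Clec12a. Hoxd10, a homeobox gene, ran from 6.53 in U118 to 9.90 in U251M2, and Aqp1, a water channel, from 7.37 in DBM2 to 9.62 in U118. Hmcn1 ran from 5.14 in U251M2 to 10.56 in U118, Cnksr2 from 4.95 in SF295 to 7.24 in DBM2, and Clec12a from 5.51 in DBM2 to 9.16 in U118. Mouse Met differed between lines (adjusted p = 1.99e-08, limma), from 5.87 in U251M2, also the lowest line for human MET, to 6.90 in U118. Mouse Hgf differed as well (adjusted p = 0.046, limma), and its call was lost when single arrays were left out in 17 of 28 cases. Human RNA binding to mouse probes could add to line differences on mouse arrays, as weighed in the closing part. Line names drawn at random are compared in the closing part.

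**Figure D3:**
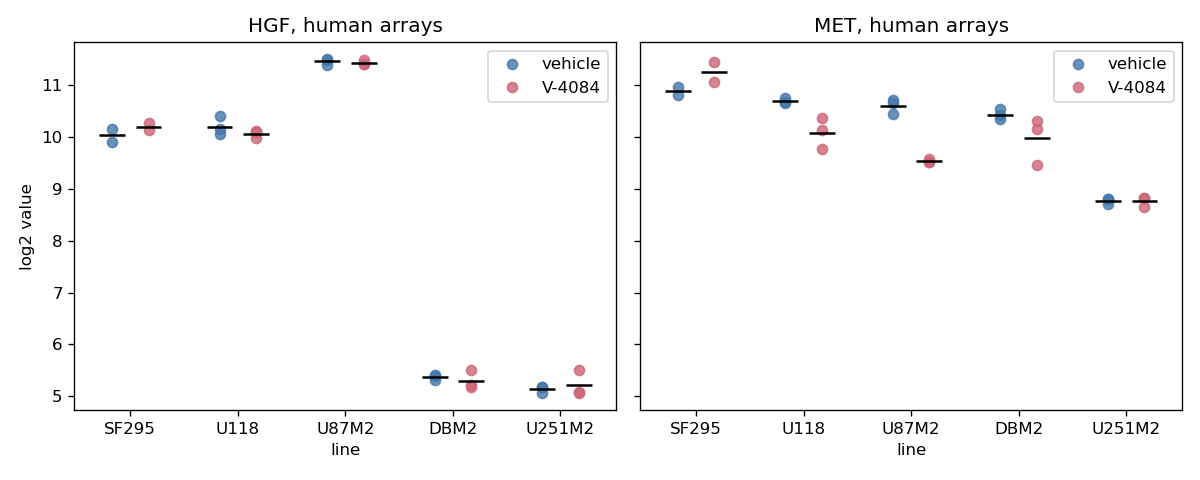
HGF (left) and MET (right) on human arrays, as log2 values (y axis) by line (x axis); points are arrays coloured by treatment and bars are group means. HGF lies above 10 in SF295, U118 and U87M2 on average and near 5 in DBM2 and U251M2, and MET in U87M2 moves from 10.60 to 9.54.

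In U87M2, V-4084 was followed by lower expression of growth factor signalling output and cholesterol synthesis genes and by higher expression of FOXO targets and fibroblast markers on human arrays. MET fell by 1.06 (SE 0.16, n = 3 and 3; adjusted p = 3.13e-05, limma) and HGF differed by -0.03 (SE 0.12, adjusted p = 0.919). In all, 2760 genes were called, 989 higher and 1771 lower, and 1421 of them differed at least 1.5-fold. The largest increases were in OGN (6.94-fold), a matrix proteoglycan, ASPN (6.53-fold), another, CYP1B1 (6.30-fold), a cytochrome P450, and ABCA6 (6.08-fold), a lipid transporter. The vehicle mean of ASPN (5.13) lay near that of the lowest line (5.03 in U251M2). Those of OGN (4.99) and ABCA6 (5.38) were low but lay above the lowest lines (4.30 in DBM2 and 4.27 in U118). Signal over background was not analysed, so these folds and their order are not shown to be measured above background. The largest decreases were in SULT1B1 (9.42-fold), a sulfotransferase, which went from 7.69 to 4.46, near its vehicle means of 3.81 to 4.06 in SF295, U118 and U251M2, with signal over background not analysed here. They were followed by EPHA2 (5.51-fold), a receptor kinase, STC1 (5.46-fold), a secreted hormone, and HMGA1 (5.08-fold), a chromatin protein. Without vehicle repeat 3, 1750 genes were called, and without the 3 narrow-range arrays 4816.

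Of 22 MAPK output genes, which are transcribed after ERK activation, 17 fell and 1 rose in U87M2 (19 adjusted over the list alone; camera adjusted p = 3.14e-18, and adjusted p = 0.00151 with an estimated correlation). FOSL1 fell by 2.08 (SE 0.12), LIF by 1.57 (SE 0.15) and EGR1 by 1.80 (SE 0.19). Of 18 cholesterol synthesis genes 17 fell (17 adjusted over the list alone; adjusted p = 0.0103 with an estimated correlation), among them HMGCS1, which fell by 1.69 (SE 0.12), and DHCR7, which fell by 1.90 (SE 0.20). Of 15 FOXO targets, which are transcribed when AKT signalling is low, 7 rose and 1 fell (10 adjusted over the list alone; adjusted p = 0.0103 with an estimated correlation). BCL2L11, a cell death gene, rose by 1.89 (SE 0.17) and SESN3 by 1.85 (SE 0.19). Of 13 fibroblast genes 8 rose (8 adjusted over the list alone; adjusted p = 0.00803 with an estimated correlation), with DCN up by 1.97 (SE 0.15) and LUM by 1.75 (SE 0.20). Another list also holds 6 of these 13. Of 26 extracellular matrix and TGF-beta targets 15 rose and 1 fell (19 adjusted over the list alone), with BGN up by 1.48 (SE 0.16) and COL3A1 by 1.34 (SE 0.16), and adjusted p = 0.155 with an estimated correlation. Fibroblast scores tracked between platforms, as given above. The fibroblast and matrix increases, those of OGN and ASPN included, are therefore not shown to come from human cells. Mouse RNA binding to human probes was not tested.

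Of 26 G2/M cell cycle genes 22 fell in U87M2 on human arrays (25 adjusted over the list alone; adjusted p = 0.421 with an estimated correlation), with PLK1, a mitotic kinase (2.16-fold), and CENPE (2.42-fold) among them. Of 21 G1/S cell cycle genes 4 fell (9 adjusted over the list alone; adjusted p = 0.751 with an estimated correlation), among them CDC6 at -0.50 (SE 0.14). Of 26 hypoxia and glycolysis genes 17 fell and 1 rose (18 adjusted over the list alone; adjusted p = 0.421 with an estimated correlation), with VEGFA at -1.46 (SE 0.21) and HK2, a hexokinase, at -1.37 (SE 0.18). Of 24 ATF4 and unfolded protein response genes 8 fell (10 adjusted over the list alone; adjusted p = 0.676 with an estimated correlation), with SLC7A5, an amino acid transporter, at -1.64 (SE 0.18). Of 10 antigen presentation genes 6 fell (6 adjusted over the list alone; adjusted p = 0.0938 with an estimated correlation), with TAP1 at -0.50 (SE 0.12) and PSMB8 at -0.74 (SE 0.15). Of 28 inflammatory genes 7 fell and 2 rose (10 adjusted over the list alone; adjusted p = 0.488 with an estimated correlation): CXCL8, a chemokine, at -1.57 (SE 0.24) and PTGS2 at -1.34 (SE 0.19) fell, and VCAM1, an adhesion molecule, rose by 1.24 (SE 0.18). These 11 of 30 lists were called by camera, 4 of them with an estimated correlation, and 13 by fry.

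Averaged over the 5 lines, 25 of 26 G2/M genes and 15 of 18 cholesterol synthesis genes fell on human arrays, with list tests at adjusted p = 0.0774 and 0.0282 with an estimated correlation. MET fell by 0.35 (SE 0.08, adjusted p = 0.00454, limma, BH), and HGF differed by 0.00 (adjusted p = 0.965). The MET difference was negative in 4 of 5 lines, with -0.01 in U251M2, and was 0.37 in SF295. Among single lines MET was called in U87M2 alone. Of 2138 called genes 623 were higher and 1515 lower, 1051 had the same sign in all 5 lines and 32 differed at least 1.5-fold. The largest increases with the same sign in 5 lines were OGN (1.82-fold), EPYC (1.61), CYP1B1 (1.60), DCN (1.57), SCN7A (1.53), NDST4 (1.47), ABI3BP (1.46), MMP13 (1.44), KLRC4-KLRK1 (1.40) and NRIP2 (1.38). The largest decreases were SCD (1.73-fold), a fatty acid desaturase, CENPE (1.64), DEPDC1 (1.61), CDCA2 (1.59), CCNB1 (1.59), DLGAP5 (1.57), BUB1 (1.57), CENPF (1.57), KIF18A (1.53) and KIF11 (1.53), of which CENPE, CCNB1, BUB1, CENPF, KIF18A and KIF11 act in mitosis. Without U87M2 limma called 0 genes, with 3412 at an unadjusted p under 0.05. In that fit OGN differed by 0.39 (SE 0.10) in place of 0.87 (SE 0.09). CENPF differed by -0.64 (SE 0.12) in place of -0.65 (SE 0.10), so sizes moved for some genes and not for others. CYP1B1 rose by 2.66 in U87M2 against 0.03 to 0.30 in the other lines, SCN7A by 2.46 against 0.09 to 0.21 and NRIP2 by 1.81 against 0.03 to 0.25. Their averages thus mostly reflect U87M2. By contrast, ABI3BP was also called in U118 (0.83), and MMP13 differed by 1.10 in SF295 without a call. Outside U87M2 several of these genes were dim, with vehicle means of 4.03 to 4.25 for SCN7A and 4.18 to 4.91 for NDST4. Their vehicle means in U87M2 were 4.593 and 4.475, so folds and ranks of such dim genes are not shown to be measured above background. Dim genes also lay higher on the narrow-range V-4084 arrays, so a shared sign in 5 lines is not by itself an effect of V-4084 in each. The call of KLRC4-KLRK1 was lost without the 3 narrow-range arrays. Leaving out an array gave 1316 (SF295 vehicle 2), 1319 (DBM2 vehicle 2), 1322 (U87M2 vehicle 3), 1347 (U118 V-4084 3), 1376 (U118 vehicle 3), 1388 (U87M2 V-4084 1) or 4146 genes (DBM2 V-4084 3).

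By list, 25 of 26 G2/M genes fell on average (26 adjusted over the list alone), with MKI67 at -0.43 (SE 0.06) and HMMR at -0.60 (SE 0.09), and adjusted p = 0.0774 with an estimated correlation. Without U87M2 the median of this list was -0.47 and camera called it (adjusted p = 1.81e-25, and adjusted p = 0.24 with an estimated correlation). Among the remaining lines SF295, DBM2 and U251M2 each hold a narrow-range array. Of 18 cholesterol synthesis genes 15 fell (16 adjusted over the list alone; adjusted p = 0.0282 with an estimated correlation), with HMGCS1 at -0.56 (SE 0.06) and MSMO1 at -0.56 (SE 0.10). Of 21 G1/S genes 11 fell (15 adjusted over the list alone; adjusted p = 0.291 with an estimated correlation). Of 22 MAPK output genes 6 fell and 1, SPRY1, rose (9 adjusted over the list alone; adjusted p = 0.159 with an estimated correlation), of 26 hypoxia genes 7 fell (9 alone), and of 24 ATF4 genes 6 fell (9 alone). Of 13 fibroblast genes 4 rose (8 adjusted over the list alone; adjusted p = 0.0282 with an estimated correlation), and of 26 matrix genes 4 rose (8 alone). The neutrophil, natural killer and T cell, mast cell and adipocyte lists were called higher with list medians of 0.11, 0.13, 0.17 and 0.11, and 0, 1, 0 and 0 called genes (0, 3, 2 and 3 alone). The hypoxia, ATF4, matrix and these 4 lists all had adjusted p = 0.463 with an estimated correlation. Dim genes lay higher on the 3 narrow-range V-4084 arrays, and without those arrays 9 lists were called in place of 12. Fry called 10. Without U87M2, 5 lists were called by camera: G2/M, G1/S (median -0.17; adjusted p = 0.419 with an estimated correlation) and cholesterol synthesis (-0.18; 0.369) lower, and inflammatory (0.14; 0.24) and natural killer lists (0.15; 0.501) higher. In that fit MAPK output turned to a median of 0.07 (camera adjusted p = 0.0919), and matrix (-0.01, 0.845), hypoxia (-0.02, 0.67), ATF4 (-0.06, 0.2), fibroblast (0.09, 0.0919), neutrophil (0.12, 0.068), mast cell (0.18, 0.0641) and adipocyte lists (0.10, 0.068) were not called.

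The other 18 lists were not called for the human average by camera. Adjusted p was 0.433 for the HGF-MET axis, 0.0673 for FOXO targets, 0.806 for interferon response, 0.228 for antigen presentation, 0.198 for inflammatory cytokines, 0.381 for p53 targets, 0.492 for neural and glial identity, 0.215 for growth factor receptors and 0.722 for angiogenesis. Among cell types it was 0.562 for endothelial, 0.466 for pericyte, 0.139 for macrophage, 0.103 for B cell, 0.133 for dendritic cell, 0.941 for skeletal muscle, 0.212 for keratinocyte, 0.399 for erythroid and 0.466 for Schwann and nerve. The median of the HGF-MET axis was 0.004 while its mean was -0.046 and its test pointed down.

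**Figure D4:**
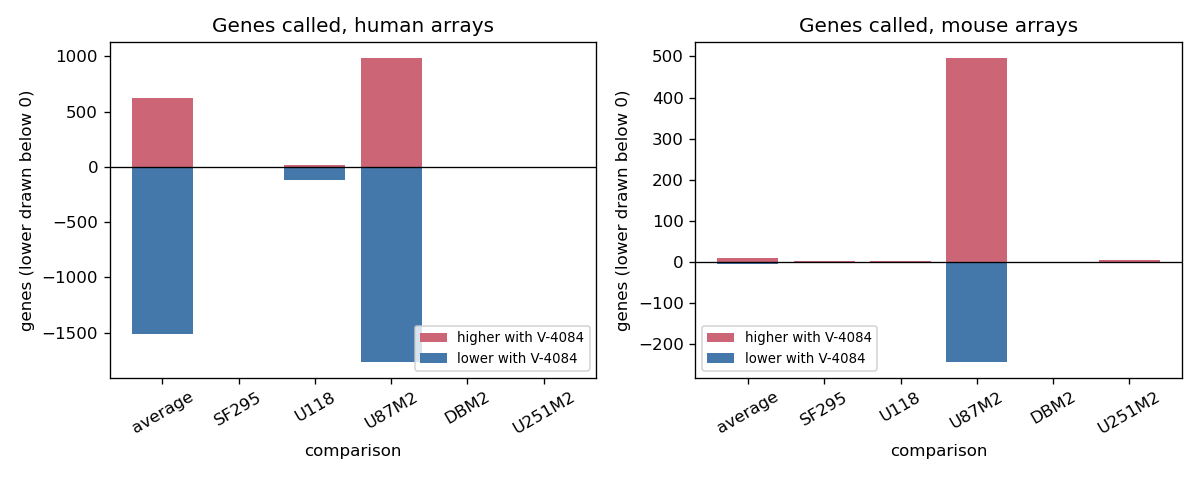
Number of genes called at an adjusted p under 0.05 (limma, BH; y axis), those lower with V-4084 drawn below 0, for the average and each line (x axis) on human (left) and mouse (right) arrays. U87M2 has 2760 calls on human and 741 on mouse arrays.

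In U118, V-4084 was followed by lower G2/M and cholesterol synthesis genes on human arrays. Of 139 called genes 20 were higher and 119 lower. Increases were largest in CAPN6 (2.16-fold), ABI3BP (1.78), CDH10 (1.73) and PDK4 (1.64), a mitochondrial kinase that limits glucose use. Decreases were largest in SCD (2.79-fold), H1-5 (2.70), a linker histone, KIF11 (2.26) and KIF15 (2.16), which are mitotic motors. The sizes of SCD and CDH10 rested on vehicle repeat 2, without which they differed by -0.87 and 0.47 (adjusted p = 0.0868 and 0.324, limma). Of 26 G2/M genes 13 fell (25 adjusted over the list alone), with MKI67 at -0.81 (SE 0.13), and of 21 G1/S genes 3 fell (16 alone), with RRM2 at -0.92 (SE 0.16), both at adjusted p = 0.0712 with an estimated correlation. Of 18 cholesterol synthesis genes 7 fell (11 adjusted over the list alone; adjusted p = 0.0404 with an estimated correlation). MET differed by -0.61 (SE 0.16, n = 3 and 3; adjusted p = 0.0767, limma), was called without V-4084 repeat 2 (adjusted p = 0.0349, limma) or without the narrow-range arrays (0.00177), and HGF differed by -0.14 (adjusted p = 0.684). The skeletal muscle list was called lower with a median of -0.21 (adjusted p = 0.793 with an estimated correlation), and TTN was its called gene. Hypoxia was called lower, and inflammatory, natural killer and adipocyte lists higher, with adjusted p of 0.818, 0.623, 0.793 and 0.751 with an estimated correlation. Leaving out vehicle 2, vehicle 3, V-4084 1 or V-4084 3 gave 21, 2, 7 or 6 genes, and of the 8 named genes CAPN6 kept its call each time, as the only one to do so. Without the 3 narrow-range arrays 608 genes were called.

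In SF295, DBM2 and U251M2, limma called 0 genes on human arrays, with 1581, 4920 and 1110 at an unadjusted p under 0.05. MET differed by 0.37 (SE 0.20, n = 2 and 2; adjusted p = 0.605, limma), -0.46 (SE 0.16, n = 3 and 3; adjusted p = 0.115) and -0.01 (SE 0.16, adjusted p = 0.99), and HGF by 0.17, -0.07 and 0.08 (adjusted p = 0.745, 0.718 and 0.829). The G2/M list was called lower in all 3, with medians of -0.36, -0.44 and -0.29, and 0 called genes in each (6, 11 and 0 adjusted over the list alone). With an estimated correlation its adjusted p was 0.751, 0.751 and 0.763. SF295 had MAPK output and inflammatory lists higher (medians 0.10 and 0.24) and the endothelial list lower (-0.18), at adjusted p = 0.434, 0.0901 and 0.751 with an estimated correlation. DBM2 had the ATF4 list lower (-0.11) and natural killer and mast cell lists higher (0.23 and 0.29), at adjusted p = 0.808, 0.751 and 0.751 with an estimated correlation. U251M2 had G1/S lower (-0.20) and MAPK output, hypoxia, inflammatory and macrophage lists higher (0.10, 0.17, 0.11 and 0.13), at adjusted p = 0.751, 0.488, 0.763, 0.488 and 0.313 with an estimated correlation. Each of these lines holds a narrow-range array, on which bright genes lay lower relative to dim ones. Such an array can add to the fall of a list of bright genes, and G2/M medians without these arrays are not given here. After quantile normalization the G2/M medians were -0.34, -0.33 and -0.24 in SF295, DBM2 and U251M2. MET in DBM2 was called without V-4084 repeat 3 (adjusted p = 0.014, limma), and without V-4084 repeat 2, the narrow-range array, its difference was -0.20 and was not called. Without SF295 V-4084 repeat 1 the SF295 count was 1918 and without DBM2 V-4084 repeat 3 the DBM2 count was 4537, and without the narrow-range arrays all 3 counts were 0. Array weights gave 1976 genes in DBM2 (730 higher, 1246 lower).

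**Figure D5:**
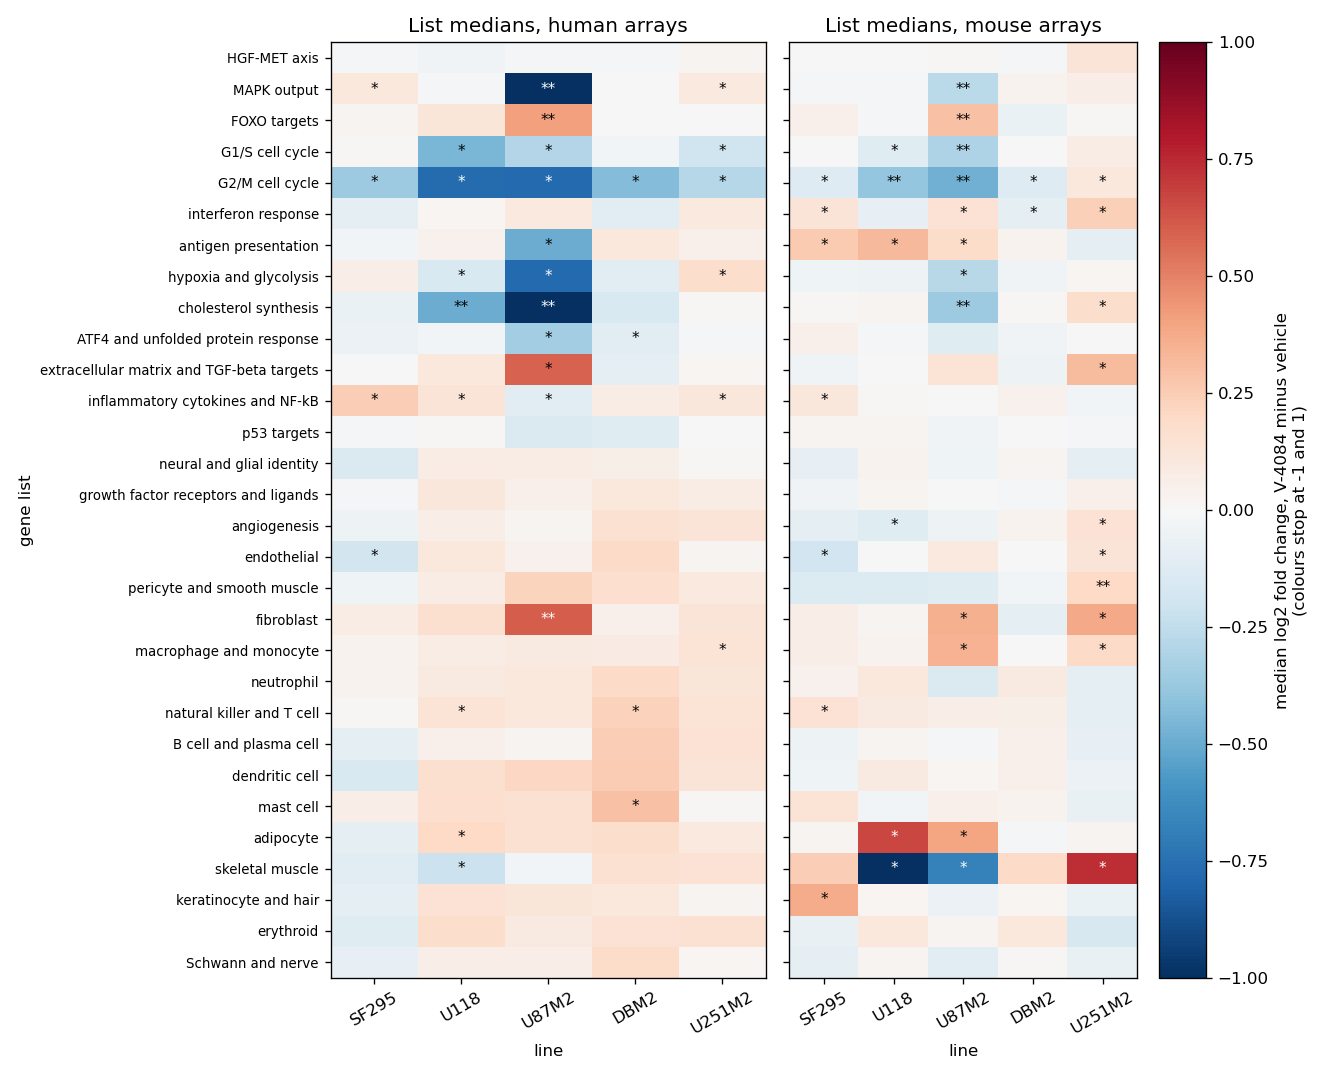
Median log2 fold change (V-4084 minus vehicle; colour) of each of the 30 lists (y axis) by line (x axis) on human (left) and mouse (right) arrays. A star marks lists called by camera and 2 stars those also called with an estimated correlation.

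The effect of V-4084 differed between lines for 1019 human genes by limma's F test. The smallest p belonged to FOSL1 (adjusted p = 1.31e-09), ABCA6 (6.28e-09), CYP1B1 (1.26e-08), PTCH1 (1.26e-08), the Hedgehog receptor, HEY1 (1.26e-08), a Notch target, and ADGRL2 (1.43e-08). FOSL1 fell by 2.08 in U87M2 and differed by -0.08 to 0.43 in the other 4 lines, where it was not called. PTCH1 rose by 1.84 in U87M2 and differed by -0.14 to 0.24 elsewhere, and HEY1 rose by 1.74 against -0.23 to 0.05. MET differed as well (adjusted p = 0.00286), and HGF was not called (adjusted p = 0.724). Against the mean of the other lines, a contrast chosen after the data were seen, 1617 genes differed in U87M2 (709 higher, 908 lower). In that contrast 11 lists were called, 7 with an estimated correlation, among them MAPK output, with 17 of 22 genes lower, and FOXO targets, with 7 of 15 higher. Without U87M2, 0 genes differed between the other 4 lines by limma, with 1256 at an unadjusted p under 0.05. The count was 2620 without SF295 V-4084 repeat 1, 667 without U87M2 V-4084 repeat 2 and 1888 without the narrow-range arrays.

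On the mouse arrays of U87M2, cell cycle, MAPK output and cholesterol synthesis genes fell and FOXO targets rose. Human RNA binding to mouse probes is not excluded as a source, as weighed in the closing part. Of 741 called genes 497 were higher and 244 lower, and after quantile normalization 514 were higher and 517 lower. The largest increases were Klk1b22 (2.91-fold), Cyp2e1 (2.89), Ms4a4a (2.58) and Abca1 (2.48), a cholesterol exporter. The largest decreases were Kcne3 (2.95-fold), Apln (2.64), the ligand of a vascular receptor, Ch25h (2.30), which makes 25-hydroxycholesterol, and Cxcl14 (2.30), a chemokine. Cyp2e1 lost its call without vehicle 2, V-4084 2 or V-4084 3 (adjusted p = 0.071, 0.11 and 0.057, limma). Of 25 G2/M genes 16 fell (23 adjusted over the list alone; adjusted p = 0.0303 with an estimated correlation), with Plk1 at -0.81 (SE 0.12), and of 21 G1/S genes 8 fell (17 alone; adjusted p = 0.000833 with an estimated correlation). Of 24 MAPK output genes 10 fell (13 alone; adjusted p = 0.00649 with an estimated correlation), with Spry2 at -0.77 (SE 0.10) and Spry4 at -0.85 (SE 0.13), which are feedback inhibitors. Of 19 cholesterol synthesis genes 7 fell (11 alone; adjusted p = 0.022 with an estimated correlation), and of 14 FOXO targets 5 rose (9 alone; adjusted p = 0.0368 with an estimated correlation), among them Txnip at 0.60 (SE 0.13). Mouse Met and Hgf differed by 0.17 and 0.29 (adjusted p = 0.352 and 0.238).

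Among markers of host cells on the mouse arrays of U87M2, of 17 macrophage and monocyte genes 5 rose and 1 fell (12 adjusted over the list alone; adjusted p = 0.59 with an estimated correlation). Tyrobp rose by 0.67 (SE 0.14), C1qa by 0.64 (SE 0.14), and Csf1r, the receptor of a macrophage growth factor, by 0.53 (SE 0.13), while Ccr2, a monocyte receptor and the member that fell, chosen after its values were seen, fell by 0.88 (SE 0.22). Of 15 endothelial genes 3 rose and 1 fell (5 alone) and the list was not called. Sox17 rose by 0.79 (SE 0.12), Vwf by 0.55 (SE 0.12) and Tek by 0.43 (SE 0.11), and Cldn5, a tight junction gene, fell by 1.06 (SE 0.15). Of 19 angiogenesis genes 1 rose and 3 fell (6 alone) without a call of the list, with Angpt2 at -1.13 (SE 0.23), Adamts1 at -1.16 (SE 0.11), Apln at -1.40 (SE 0.20) and Aplnr, the receptor of Apln, up by 0.80 (SE 0.13). Of 26 interferon genes 5 rose (8 alone; adjusted p = 0.698 with an estimated correlation), with Oas2 at 0.76 (SE 0.15), and of 12 antigen presentation genes 2 rose, H2-Aa and B2m (2 alone; adjusted p = 0.799 with an estimated correlation). Of 24 hypoxia genes 7 fell (9 alone; adjusted p = 0.308 with an estimated correlation), with Vegfa at -0.67 (SE 0.11). The fibroblast, adipocyte and skeletal muscle lists were called with medians of 0.35, 0.39 and -0.67 and 0 called genes each (0, 2 and 0 alone), at adjusted p = 0.698, 0.698 and 0.859 with an estimated correlation. With the muscle score as covariate 758 genes were called. Leaving out vehicle 1, vehicle 3, V-4084 1 or V-4084 2 gave 398, 413, 372 or 411 genes.

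In the other lines few mouse genes were called. In SF295 Ch25h rose by 1.34 (SE 0.18, n = 2 and 3, adjusted p = 0.00133, limma) and Klra2, a lectin-like receptor, by 1.03 (SE 0.12, adjusted p = 0.000178). In U118 Fam13a rose by 0.99 (SE 0.14, n = 3 and 3; adjusted p = 0.00526, limma) and Adig, an adipocyte gene, by 1.03 (SE 0.17; adjusted p = 0.0184). In U251M2, with 3 and 2 arrays, 5 genes rose and 3 fell by limma, among them Tagln, a smooth muscle gene, at 0.95 (SE 0.18), Tspan4 at 0.70 (SE 0.13), Isg20l2 at 0.62 (SE 0.11) and Psmb3 at 0.50 (SE 0.09), with Dnah7b at -0.90 (SE 0.14) and Upb1 at -0.49 (SE 0.09). In DBM2 limma called 0 genes, with 458 at an unadjusted p under 0.05. Mouse Met differed by 0.19, -0.16, -0.01 and 0.18 in SF295, U118, DBM2 and U251M2 (adjusted p = 0.74, 0.778, 1 and 0.398, limma), and Hgf by 0.02, -0.01, -0.17 and 0.13 (adjusted p = 0.988, 0.996, 1 and 0.684). Without U251M2 V-4084 repeat 2 Tagln differed by 0.60 (SE 0.20). Klra2 kept its call whichever array was left out, Ch25h lost it without vehicle 1, Adig without 4 of 6 arrays, Fam13a without 2 of 6, Dnah7b without 2 of 5 and the other named U251M2 genes without at least 4 of 5. Leaving out an array gave 9 (vehicle 2) or 5 genes (V-4084 3) in SF295. It gave 1 (vehicle 1), 0 (vehicle 2), 5 (vehicle 3), 18 (V-4084 1), 0 (V-4084 2) or 1 (V-4084 3) in U118, and 4 (vehicle 1), 1 (vehicle 2), 0 (vehicle 3), 53 (V-4084 1) or 0 (V-4084 2) in U251M2.

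By list, of the 25 mouse G2/M genes in U118 0 were called by limma and 21 fell adjusted over the list alone (list median -0.39; adjusted p = 0.0368 with an estimated correlation). The adipocyte list was higher in U118 (median 0.67, 0 called and 7 alone; adjusted p = 0.157 with an estimated correlation) and the skeletal muscle list lower (median -1.72, 0 called and 0 alone; adjusted p = 0.585 with an estimated correlation). The muscle score in U118 was 8.71, 9.95 and 8.61 with vehicle and 6.27, 9.59 and 6.23 with V-4084, so it varied within groups, and with this score as covariate 69 genes were called in U118 (9 higher, 60 lower). G1/S and angiogenesis lists were lower and antigen presentation higher in U118, at adjusted p = 0.0929, 0.594 and 0.601 with an estimated correlation. In U251M2 the pericyte list was higher (median 0.20, 0 called and 1 alone; adjusted p = 0.0303 with an estimated correlation), with Cspg4 at 0.50 (SE 0.12). The G2/M, interferon, cholesterol, matrix, angiogenesis, endothelial, fibroblast, macrophage and skeletal muscle lists were also higher in U251M2, at adjusted p of 0.698, 0.59, 0.12, 0.59, 0.59, 0.601, 0.59, 0.594 and 0.83 with an estimated correlation. In SF295 G2/M and endothelial lists were lower and interferon, antigen presentation, inflammatory, natural killer and keratinocyte lists higher, and the adjusted p with an estimated correlation was 0.698, 0.594, 0.799, 0.698, 0.193, 0.59 and 0.601. The keratinocyte list had a median of 0.37, with Krt5 at 1.22 (SE 0.60, adjusted p = 0.743). In DBM2 G2/M and interferon lists were lower, at adjusted p = 0.698 and 0.675 with an estimated correlation.

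Averaged over the 5 lines, 14 mouse genes were called, 10 higher and 4 lower, 4 of them with the same sign in all 5 lines. Abca1 (0.33, SE 0.05), Per1 (0.33, SE 0.06), a clock gene, Pde7b (0.32, SE 0.06), Phyhd1 (0.30, SE 0.06) and Aqp1 (0.29, SE 0.05) rose. Dpf3 (-0.19, SE 0.04), Knstrn (-0.28, SE 0.05) and Ect2 (-0.30, SE 0.06), which act in cell division in the case of Knstrn and Ect2, and Eif2s2 (-0.29, SE 0.06), a translation factor, fell, and Plk1 had -0.27 (SE 0.06; adjusted p = 0.0898, limma). Met and Hgf differed by 0.07 and 0.05 (adjusted p = 0.551 and 0.808). Without U87M2 limma called 0 genes, with 1070 at an unadjusted p under 0.05, and Knstrn differed by -0.24 (SE 0.05) and Abca1 by 0.09 (SE 0.05). Leaving out 1 of the 28 arrays ended the call of Dpf3 in 24 cases, Ect2 and Eif2s2 in 23 each, Aqp1 in 15, Phyhd1 in 13, Pde7b in 12, Per1 in 11 and Abca1 and Knstrn in 3 each. Plk1 was called without U87M2 vehicle 2 (adjusted p = 0.0493, limma) or DBM2 vehicle 2 (0.0341). Leaving out an array gave 0 genes (SF295 vehicle 1, U118 V-4084 3 or U251M2 V-4084 2), 3 (U87M2 V-4084 1), 4 (U118 vehicle 3 or U87M2 V-4084 2), 5 (U118 vehicle 2, U118 V-4084 1, DBM2 vehicle 1, DBM2 vehicle 3 or DBM2 V-4084 1) or 6 (U87M2 vehicle 3). It gave 7 (U251M2 vehicle 1 or 3), 8 (SF295 V-4084 1 or DBM2 V-4084 3), 9 (SF295 V-4084 2) or 28 (U118 V-4084 2).

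For this mouse average 13 lists were called, 4 lower and 9 higher, with 0 called genes in each by limma. Of 25 G2/M genes 21 fell adjusted over the list alone (adjusted p = 0.0424 with an estimated correlation), and of 21 G1/S genes 1 (adjusted p = 0.0486 with an estimated correlation). MAPK output (2 lower alone) and hypoxia (1 lower alone) had adjusted p = 0.417 and 0.453 with an estimated correlation. Higher were macrophage (list median 0.13, 6 up and 1 down alone), adipocyte (0.24, 6 up alone), antigen presentation (0.11, 3 up alone), interferon (0.09, 2 up alone), FOXO targets (0.07, 1 up alone), fibroblast (0.12, 0 alone), inflammatory (0.05, 0 alone), natural killer (0.08, 0 alone) and matrix lists (0.04, 0 alone). Their adjusted p with an estimated correlation was 0.254, 0.37, 0.417, 0.453, 0.37, 0.453, 0.254, 0.459 and 0.738. Fry called 2 lists. Without U87M2, G2/M (median -0.11; adjusted p = 0.407 with an estimated correlation) and the macrophage, adipocyte, antigen presentation, inflammatory, interferon, matrix and fibroblast lists (adjusted p = 0.44, 0.44, 0.676, 0.407, 0.714, 0.714 and 0.676 with an estimated correlation) stayed called by camera. In that fit G1/S (-0.01, camera adjusted p = 0.996), hypoxia (-0.02, 0.949), FOXO targets (0.00, 0.969), MAPK output (0.02, 0.111) and natural killer lists (0.04, 0.167) were not called. Cholesterol synthesis and keratinocyte lists were then called higher (0.03 and 0.14; adjusted p = 0.407 and 0.761 with an estimated correlation). Not called were the HGF-MET axis (adjusted p = 0.339), cholesterol synthesis (0.575), ATF4 (0.725), p53 targets (0.409), neural identity (0.189), growth factor receptors (0.575), angiogenesis (0.402), endothelial (0.417), pericyte (0.575), neutrophil (0.649), B cell (0.601), dendritic cell (0.175), mast cell (0.33), skeletal muscle (0.12), keratinocyte (0.142), erythroid (0.649) and Schwann lists (0.328). The median and the test of the HGF-MET axis, p53, angiogenesis and erythroid lists differed in sign in this average.

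The effect differed between lines for 68 mouse genes by limma's F test. The smallest p belonged to Adamts1, Ch25h and Kcng1 (adjusted p = 6.25e-05 each), Abca1 (0.000152), Klk1b22 (0.000434) and Odc1 (0.00351), an enzyme of polyamine synthesis. Ch25h rose by 1.34 in SF295 and fell by 1.21 in U87M2, both called, and the call in SF295 was lost without SF295 vehicle repeat 1 (adjusted p = 0.236, limma). Abca1 rose by 1.31 in U87M2 and differed by -0.07 to 0.21 in the other lines, and Odc1 fell by 0.89 in U87M2 and differed by -0.35 to 0.40 elsewhere. Met and Hgf were not called (adjusted p = 0.38 and 0.529). In U87M2 against the mean of the other lines, a later choice, 324 genes differed (213 higher, 111 lower). Without U87M2, 0 genes differed between lines by limma, with 1775 at an unadjusted p under 0.05. Leaving out U87M2 vehicle 1, vehicle 3, V-4084 1 or V-4084 2 gave 23, 28, 22 or 23 genes.

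The calls of the platforms overlapped in U87M2. Of 14334 symbols on both, 131 were higher with V-4084 on human and mouse arrays (24.5 by chance; Fisher's exact p = 3.46e-61) and 126 lower (23.7 by chance; Fisher's exact p = 3.41e-65), and 22 had opposite signs. SPRY2, SPRY4 and PLK1 fell on both, as did CAMK2N1 (-1.33 and -0.77), FADS2 (-1.82 and -0.97), a fatty acid desaturase, and ODC1 (-0.93 and -0.89). NR2F1 (0.97 and 0.87), PDE7B (1.37 and 0.94), YPEL2 (1.04 and 0.73) and HEY1 (1.74 and 0.88) rose on both. For the average, 4 genes were higher (0.255 by chance; Fisher's exact p = 6.45e-05) and 3 lower on both (0.374 by chance; Fisher's exact p = 0.00303), with KNSTRN, PDE7B, EIF2S2, ECT2, PER1 and ABCA1 among them. Across genes, log2 fold changes correlated at r = 0.319 in SF295, 0.378 in U118, 0.318 in U87M2, 0.370 in DBM2 and -0.088 in U251M2, and genes are not independent replicates. Over the 6592 genes above the median level on both platforms r was 0.494, 0.461, 0.432, 0.505 and 0.167 in that order, so the sign in U251M2 depends on the genes used. Same-numbered arrays track in muscle genes, so the overlap is not between independent samples. Human RNA binding to mouse probes could also add to the overlap, as weighed in the closing part. Fold changes from differently numbered arrays, a later choice, correlated across 14318 genes at 0.246 in U87M2 against 0.275 from same-numbered arrays, 0.231 against 0.301 in U118 and 0.086 against 0.191 in DBM2. The correlations from different numbers ran from 0.098 to 0.401, 0.138 to 0.318 and -0.135 to 0.420, ranges that hold the values from same numbers. The covariance from different against same numbers was 0.0226 against 0.0256 in U87M2, 0.0117 against 0.0147 in U118 and 0.0120 against 0.0095 in DBM2.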

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

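The tests of tracking, of a general effect of V-4084 on the range, and of human RNA or host cells on the mouse arrays were chosen after the results were seen, while the test of array quality and the splits of the samples were not. The effect of V-4084 differed between lines by an F test for 1019 human genes and 68 mouse genes, which is why these results and the named genes among them are listed here. On human arrays the adjusted p of this test (limma, BH) was 1.31e-09 for FOSL1, 6.28e-09 for ABCA6, 1.26e-08 for CYP1B1, PTCH1 and HEY1, 1.43e-08 for ADGRL2, 1.03e-07 for HMGA1, 1.21e-07 for STC1, 3.83e-07 for EPHA2, 6.53e-07 for SULT1B1, 7.17e-07 for OGN and 8.4e-07 for SCN7A. It was 3.92e-06 for NRIP2, 6.72e-06 for DCN, 6.05e-05 for NDST4, 7.64e-05 for ASPN, 0.000109 for EPYC, 0.000196 for PDK4, 0.00153 for CAPN6, 0.00286 for MET, 0.00964 for ABI3BP, 0.0147 for SCD, 0.018 for KIF18A, 0.0187 for MMP13 and 0.0286 for CDH10. On mouse arrays it was 6.25e-05 for Adamts1, Ch25h and Kcng1, 0.000152 for Abca1, 0.000434 for Klk1b22, 0.00351 for Odc1 and Klra2, 0.0111 for Fam13a, 0.0116 for Aqp1, 0.0124 for Cxcl14, 0.019 for Per1, 0.0207 for Kcne3, 0.0238 for Plk1, 0.0358 for Ms4a4a, 0.0413 for Dnah7b and 0.0489 for Pde7b.

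Other splits of the arrays within lines were drawn for both platforms, 100 each with the real one. For the human average 1 of 100 gave as many genes as the real 2138 and the highest other gave 577. Chance can be excluded as the source of an effect in any line. The split with 577 kept the U87M2 groups whole, as labelled or exchanged, and splits that mixed U87M2 reached 4. The 13 draws that kept U87M2 whole are too few for a share under 0.05, so an effect outside U87M2 is not decided. For differences between human lines 4 of 100 gave as many genes, a share under 0.05, with 1019 real and 1301 as the highest other. The 3 others as large all kept the U87M2 groups whole, either as labelled or with vehicle and V-4084 exchanged. On both platforms these splits ask whether V-4084 has an effect in any line, not whether the effects are equal. They cannot decide whether the effects differ between lines. For the human lists chance cannot be excluded (5 of 100, 12 real and 15 as the highest other). The 4 others as large all kept the U87M2 groups whole in the same sense, though, and splits that mixed U87M2 reached 11. For vehicle levels chance can be excluded on both platforms, at 1 of 100 each (10764 real and 3110 as the highest other on human, 10833 and 3646 on mouse arrays). For the mouse average chance can be excluded as the source of an effect in any line (1 of 100, 14 real and 3 as the highest other). The split with 3 kept the U87M2 groups whole, and splits that mixed U87M2 reached 1. The 9 draws that kept U87M2 whole are too few for a share under 0.05, so an effect outside U87M2 is not decided. For differences between mouse lines chance cannot be excluded (9 of 100, 68 real and 290 as the highest other). The 8 others as large all kept the U87M2 groups whole in the same sense, a structure of the samples, and splits that mixed U87M2 reached 3. For the mouse lists chance cannot be excluded (10 of 100, 13 real and 15 as the highest other, which mixed U87M2). Lines with 3 arrays a group have 10 splits, too few for a share under 0.05. There the real value and the highest other were 139 and 0 in U118, 2760 and 1 in U87M2, 0 and 1 in DBM2 and 0 and 1 in U251M2 on human arrays, with 1, 1, 10 and 10 splits as large. On mouse arrays they were 2 and 13 in U118, 741 and 5 in U87M2 and 0 and 1 in DBM2, with 4, 1 and 10 splits as large.

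Same-numbered human and mouse arrays deviated together, although the labels give cultured cells on one platform and tumours on the other. A candidate explanation is that RNA of the same tumours was hybridised to both platforms. It predicts that the 14318 genes outside the muscle list track too, and they did on vehicle arrays (mean r = 0.228 for same numbers and -0.123 for others, one-sided permutation p = 0.00122), with 10 of 12 arrays in groups of 3 closest to their own number (4 by chance). On V-4084 arrays they did not (-0.024 against 0.012, one-sided permutation p = 0.657, and 2 of 9 arrays with 3 by chance). The muscle score itself did track on V-4084 arrays alone (r = 0.957). For those arrays this explanation cannot be told apart from others. A processing day shared by a repeat number would tie vehicle to V-4084 arrays of the same number, and there the muscle score had r = -0.023 over 26 pairs, which argues against it. What stays open is a mixed-up material label, which no table here decides.

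A narrow range of values marked 3 human V-4084 arrays. Against a general effect of V-4084, 4 of the 5 other V-4084 arrays in those groups had an SD at or above the lowest vehicle array. A smaller narrowing is not excluded, since every V-4084 array was narrower than every vehicle array of its line in U118 (2.021 to 2.037 against 2.039 to 2.064) and U87M2 (2.031 to 2.053 against 2.081 to 2.096). Poor array or RNA quality may be the cause, since their deviations correlated across genes at a mean r of 0.2499. Another set of 3 arrays from the same groups reached 0.2505. Deviations are centred within small groups, so the other arrays of a group deviate the opposite way on balance and can correlate as well. The comparison of sets therefore decides nothing, and array quality cannot be told apart from other causes. No biological explanation for single arrays was tested.

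On the mouse arrays, U87M2 responded to V-4084. Human RNA binding to mouse probes could mimic a response. Of 11 called host cell markers 9 had human counterparts below the median level of the human U87M2 vehicle arrays. Markers of host cells were likely to be low there in advance, and a level under the median does not show an absent transcript. The level therefore cannot decide. On human arrays of U87M2 TEK was called (adjusted p = 0.00386, limma). The other counterparts were not (0.406 to 0.969), so no matching human change was found for those. For the other genes human RNA cannot be told apart from a host response: 92.1% of genes called on both platforms had the same sign. Binding of human RNA predicts that, and a host response would allow it. Line profiles of vehicle arrays also matched between platforms (mean r = 0.260 for the same line and -0.065 for different lines), which binding of human RNA would produce as well. Profiles are centred over the lines, which pushes the value for different lines below 0. A changed share of all host cells would move their markers alike, and of the 11 called markers 2, Cldn5 and Ccr2, fell while 9 rose, which argues against it as the whole cause. For the markers that rose it cannot be told apart, since macrophage minus endothelial scores differed by 0.103 (95% interval -0.102 to 0.309). A host response to V-4084 or to a changed tumour stays open and was not tested.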

How the results depend on the processing

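Chosen after the data were seen were the fits without the 3 narrow-range arrays, without the U87M2 line and with the muscle score. Of 173 counts under alternatives other than leaving out an array, 126 stayed within 1.5 times the count given and 47 moved, and no called named gene changed direction under any alternative. Of 190 medians of called lists under quantile normalization or centring 0 changed sign. Where no cause is given, the cause was not tested. On human arrays quantile normalization gave 1389 genes for the average, and the block for repeat numbers 1130, with 30 in U118 and 587 for differences between lines. Array weights gave 4530 in U118, 5960 in U87M2, 1976 in DBM2 and 3202 for differences. A 1.5-fold filter, which can remove calls by its construction, gave 32 for the average and 1421 in U87M2, and fits of a line alone 350 in U118 and 4286 in U87M2. Without the narrow-range arrays there were 608 in U118, 4816 in U87M2 and 1888 for differences. Without U87M2 there were 0 for the average (limma, 3412 at an unadjusted p under 0.05), 0 for differences (1256) and 5 lists.

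On mouse arrays genes above the median level gave 33 for the average, 1 in SF295, 0 in U118, 3 in U251M2, 114 for differences and 6841 for vehicle levels, from fewer genes tested. Averaged probe sets gave 9 and 0 for the average and U251M2, and median centring 4 for the average. Quantile normalization gave 1 in U118, 3 in U251M2 and 133 for differences, and the trend setting 3 in U251M2. Array weights gave 1171 in U87M2, 2 in U251M2 and 175 for differences, and the block 1 in SF295, 0 in U251M2 and 19 for differences. The fold filter gave 3 for the average, 270 in U87M2, 5 in U251M2 and 3818 for vehicle levels, and fits of a line alone 0 in SF295, 0 in U118 and 1 in U251M2. Without U87M2 there were 0 for the average (limma, 1070 unadjusted) and 0 for differences (1775), and the muscle score gave 69 in U118.

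Leaving out each array, on human arrays the average ran from 1316 to 4146, differences from 667 to 2620, lists from 9 to 13, vehicle levels from 10177 to 11615, SF295 from 0 to 1918, U118 from 2 to 163, U87M2 from 1750 to 2507, DBM2 from 0 to 4537 and U251M2 from 0 to 0. On mouse arrays the average ran from 0 to 28, differences from 22 to 89, lists from 10 to 14, vehicle levels from 8602 to 11399, SF295 from 2 to 9, U118 from 0 to 18, U87M2 from 372 to 798, DBM2 from 0 to 0 and U251M2 from 0 to 53. A lone array left in a group is assumed to vary like the other groups. The shared response was 5 genes for the average and 183 in U87M2 over genes above the median level, against 7 and 257. Of 3167 values for named genes, 969 kept their side and direction under the other alternatives, 109 lost their call, 5 gained one and 12 moved, and leaving out arrays gave 1839, 205, 4 and 24. Signal over background was not analysed here.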

Other observations

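The contrast of U87M2 with the other lines, the comparison of line profiles across platforms and the removal of components were chosen after the data were seen, while the lists within U87M2 were not. In U87M2 against the mean of the other lines, human arrays showed 6 of 10 antigen presentation genes lower (list adjusted p = 0.0152 with an estimated correlation) and 8 of 28 inflammatory genes lower with 2 higher (adjusted p = 0.027 with an estimated correlation). Of 33 growth factor receptors and ligands, 5 rose and 6 fell in U87M2 with no call of the list (adjusted p = 0.746). EREG, a ligand of the EGF receptor, fell by 2.16 (SE 0.16) and AXL, a receptor kinase, by 1.16 (SE 0.13), while ROR1 rose by 1.27 (SE 0.13). Of 22 neural and glial genes 3 rose (adjusted p = 0.074), among them PDGFRA (2.47-fold) and GAP43 by 1.48 (SE 0.20). On mouse arrays Mertk, a receptor of phagocytes, rose by 1.10 (SE 0.16) and Clec9a, a dendritic cell receptor, by 0.96 (SE 0.18).

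Line profiles on vehicle arrays, centred over the 5 lines, correlated across 14334 genes at a mean r of 0.260 between human and mouse arrays of the same line and -0.065 between different lines (one-sided exact permutation p = 0.00833, the smallest that 120 orders of the lines can give). After removal of 2 components of the other genes, the muscle scores of same-numbered arrays had r = 0.231, but these components carry the muscle signal (r of size 0.928 with the mouse and 0.611 with the human score), so this value decides nothing.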
